A study of Mus musculus with 9 samples.

How the data were processed

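Gene expression was measured in 9 samples of mouse brain, 1 array each, in 3 groups of 3. The groups are microvascular fragments of embryos at embryonic day 18.5, the brain tissue of embryos of that age without the fragments (rest of brain), and microvascular fragments of adults aged 1 year. Per the labels, the arrays of a group are biological replicates. Per the labels' protocols, total RNA was extracted with a micro kit from embryonic and a mini kit from adult tissue, and biotin-labelled cRNA was made from about 100 ng of total RNA by the manufacturer's amplification for small samples. Embryos were of the NMRI strain and adults of a mixed C57/SV129 background, 1 female and 2 males. The sex of the embryos and the way the fragments were isolated are not given in the sources used here. The description of rest of brain replicate 3 gives its embryonic day differently from its other labels, and the sample was kept in its group.

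The deposited values are on the log2 scale, 1 per probe set and array, and were made by the authors with GCRMA 2.6.0 in R 2.4.1, per the submitters' processing notes. GCRMA corrects each probe for background by its base composition, normalizes the probes between arrays by quantiles and sums them up per probe set. That the values are log2 was read from their range, and further steps are not given in the sources used here. Scanner files and scan dates were not analysed here, so background correction from raw intensities and a block for slide or date were not run. Normalization by quantiles sets the distributions of the arrays nearly equal, so a change in the total RNA per cell cannot be seen in these values. The 9 arrays held no identical pair, and the table had 0 per-sample columns that were not used. For arrays, the number of arrays limits the precision.

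The platform table names 1 gene for 34958 of 45101 probe sets and several genes for 932, and 9211 probe sets are unnamed here, 64 of the table being control probe sets. Symbols were looked up through Entrez identifiers in a RefSeq gene table of GRCm38.p6, used for names only. This found 34754 probe sets and changed 0 symbols. Each of 18194 genes was represented by the probe set with the highest mean over the 9 arrays among those that name it alone. Control probe sets were not removed from this choice where they name a gene alone. A gene was tested where that probe set had a value of at least 4 on at least 3 of the 9 arrays, whichever these were, which left 12009 genes. Of these, 7587 had more than 1 probe set, and 1514 were represented by a probe set whose identifier marks probes shared with other transcripts. These probe sets are called open to cross-hybridization, and the alternative without them also left out probe sets shared by transcripts of the same gene. For no gene named by the rule given further on was another probe set called in the opposite direction.

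Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) with all 9 arrays in 1 fit and group as the factor, and p-values were adjusted by the Benjamini-Hochberg method over the 12009 genes of a comparison. A gene was called at an adjusted p under 0.05. The residual and prior degrees of freedom came to 8.43. Differences are log2 differences of group means with the standard error of the fit, and folds are 2 to the power of the difference. A gene under 4 on all 3 arrays of a group was treated as at background there, and "at least" folds set the mean of the other group against a value of 4. No fold is given where both groups were at background. Where 1 or 2 of the 3 arrays of a group were under 4, the fitted difference is given with that number and leans on values at background. Detection calls were not used. In medians given at the bound, members at background in 1 group were set to the bound.

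The groups, tests, filter, 21 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the alternatives, tests and lists that the closing parts name as chosen later. The lists came from textbook knowledge and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry were alternatives. For each list the members called over all genes and adjusted over the list alone were counted. The named genes of a comparison were the 5 largest differences in each direction among called genes without overlap of the arrays and a mean of at least 6 in the higher group. The differences were ranked as fitted, also where a group lay at background and the true size is known as a bound alone, so the order is not one of measured sizes. From each list they were the 2 called members with the largest differences in the direction most members took and the 1 largest in the other. Between the ages, the 5 largest in each direction among the genes higher in fragments of both ages were named too. Genes named outside this rule, among them uncalled members of lists and the genes of the 11 lists added later, were chosen after their values were seen. The added lists are reported among the other observations. List members that no single-gene probe set measured were left out.

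The labels number the replicates of each group. Embryonic fragments and rest of brain with the same number deviated together from their group means, with correlations across genes of 0.194, 0.199 and 0.217, whereas those of adult and embryonic fragments were 0.0325, -0.0826 and 0.214. The numbers were taken to pair the embryonic samples, and a fit with the replicate number as a block was an alternative. That block also ties adult arrays to embryonic ones of the same number, so in comparisons with adults it follows no known pairing. The other alternatives changed the filter, set a floor of 4, added an offset of 32 on the linear scale, normalized again by quantiles or cyclic loess, centred the arrays, changed the probe set of a gene or tested every probe set, fitted the compared groups alone, used a trended and robust prior or array weights, changed the threshold, and left out each array in turn. The overlap of comparisons that share the rest of brain arrays was set beside 20 simulations of unchanged groups, which leave out real effects, and beside the overlap of independent lists.

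The fit was tested on simulated data, with 200 of 12009 genes changed. For embryonic fragments against rest of brain it recovered 60.5% of them at 2-fold and 90% at 4-fold, with 11 and 5 false calls, and 0 at 1.5-fold. For adult against embryonic fragments it recovered 5.5% at 1.5-fold, 54.5% at 2-fold and 87.5% at 4-fold, with 0, 5 and 5 false calls. In the data 66.1% and 57.1% of genes were called in these comparisons, so the adjusted threshold was looser there. The simulated shares therefore do not carry over to the real comparisons. A simulated list of 20 genes raised 2-fold had a camera p of 6.52e-45, and 6 of 200 random lists had p under 0.05. The simulated genes were drawn independently of each other, so this cannot test the preset correlation for lists whose genes vary together. Control probe sets were compared by exact permutation of 3 against 3 arrays, 2-sided, for which 0.1 is the smallest p.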

Results

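Gene expression was measured in 9 samples of mouse brain on short oligonucleotide arrays, 1 array per sample. Microvascular fragments, short pieces of small blood vessels isolated from brain, came from embryos at embryonic day 18.5 (3 arrays) and from adults aged 1 year (3 arrays). The embryonic brain tissue that remained without the fragments made up the other 3 arrays and is called rest of brain. The labels describe 3 biological replicates per group, and every mean ± SD given is over n = 3 arrays. The series was designed to compare the 3 kinds of sample with each other, so each pair of groups was tested. Values are log2 intensities after GCRMA, a background correction and normalization for this type of array. The median over 45101 probe sets was 3.58 to 3.67 per array, and 47.4% to 48.1% of probe sets reached a value of 4. The number of arrays limits the precision.

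The arrays of a group resembled each other far more than those of other groups. Across the 12009 tested genes, which are not independent replicates, Pearson's r was 0.984 to 0.992 within embryonic fragments, 0.990 to 0.993 within rest of brain and 0.978 to 0.987 within adult fragments. Adult and embryonic fragments had r of 0.854 to 0.866. Embryonic fragments and rest of brain had r of 0.672 to 0.709, and adult fragments and rest of brain 0.569 to 0.601. The first principal component held 74.2% of the variance, the next held 21.2%, and the one after it 1.70%. Xist, transcribed from the inactive X chromosome, was at 13.3 on the array of the adult labelled female and at 2.77 and 2.85 on those of the adults labelled male. Eif2s3y, a gene of the Y chromosome, was at 2.92 on the former and at 11.6 and 12.6 on the latter. The labels give no sex for the embryos. Replicate 1 had Xist values of 14.6 in fragments and 13.5 in rest of brain with Eif2s3y at 3.06 and 3.04, and replicate 2 had 2.84 and 2.84 with Eif2s3y at 11.9 and 11.4. Replicate 3 showed both, with Xist at 8.13 and 6.52 and Eif2s3y at 11.9 and 11.3.

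Embryonic fragments and rest of brain shared age and strain, so this comparison asked which transcripts the vessels hold beside the remaining brain. Fragments held far more RNA of endothelial genes, of the transporters and junctions of the blood-brain barrier, of pericytes and of the vascular basement membrane, and far less of neuronal genes. With an estimated correlation the transporters kept their call (adjusted p = 0.0497 with an estimated correlation) and the other 5 lists lost it (adjusted p = 0.0650 to 0.174 with an estimated correlation). Tek, the receptor of the angiopoietins, was higher by 10.04 ± 0.28 in fragments (log2 difference ± SE; 14.08 ± 0.17 against 4.04 ± 0.63, under 4 on 2 of 3 arrays of rest of brain, limma adjusted p = 6.22e-09). Elavl3, an RNA-binding protein of neurons, was 161-fold lower (5.28 ± 0.81 against 12.61 ± 0.15, adjusted p = 2.02e-07). Markers of microglia and macrophages were higher in fragments as well (adjusted p = 0.328 with an estimated correlation). Of 12009 genes, 3473 were higher and 4466 lower in fragments (66.1% in all), and 4070 were not called. At least 2-fold differences made up 2321 of the higher and 2845 of the lower genes. Rest of brain lay under 4 on every array for 378 of the higher genes, and fragments did so for 723 of the lower ones, and for these only a bound on the fold can be given. The median difference over all tested genes was -0.10, and -0.09 after centring the arrays on their medians. The excess of lower over higher genes depended on the normalization, with 4271 higher and 4196 lower after cyclic loess. After quantile normalization once more it was 4057 higher and 4271 lower.

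The rule for named genes, which ranks fitted differences whether or not a group lay at background, picked among higher genes Icam2, an adhesion molecule of endothelium, Cyyr1, Sox17, a transcription factor of endothelial cells, Vwf, the clotting glycoprotein they store, and Tek. Icam2 (13.05 ± 0.31 in fragments) was at least 531-fold and Cyyr1 (12.92 ± 0.20) at least 484-fold higher, since rest of brain lay under 4 on every array. Sox17 and Vwf were higher by 10.23 ± 0.37 and 10.16 ± 0.19. Among lower genes it picked Slitrk1, a membrane protein of neurons, Mpped1, Soga3, Gria1, a subunit of AMPA receptors, and Lmo3. Slitrk1, Gria1, Mpped1 and Lmo3 lay under 4 on every array of fragments and were at least 131-fold, 137-fold, 87.9-fold and 54.3-fold lower. Soga3 fell by 8.23 to 3.54 ± 0.91. For Sox17, Vwf and Soga3 the dimmer group lay under 4 on 2 of 3 arrays.

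All 30 measured endothelial markers were higher in embryonic fragments, adjusted over the list alone as well as over all genes. Their median log2 difference was 8.35, or 8.02 with the members at background set to their bound (camera adjusted p = 1.18e-18, adjusted p = 0.0650 with an estimated correlation). Each of 20 transporters and receptors of the blood-brain barrier was higher, with a median of 4.18 (camera adjusted p = 5.38e-13). This list alone, of the 21 fixed ones in this and the other comparisons, kept its call with an estimated correlation (adjusted p = 0.0497). Slc38a5, a glutamine transporter, was higher by 9.54 ± 0.43 (rest of brain under 4 on 2 of 3 arrays), and Abcb1a, the drug efflux pump P-glycoprotein, by 8.91 ± 0.18. All 11 genes of tight and adherens junctions were higher, with a median of 6.60, or 6.54 at the bound (camera adjusted p = 1.76e-07, adjusted p = 0.0650 with an estimated correlation). Lsr, a protein of tricellular junctions, was higher by 8.10 ± 0.41 (rest of brain under 4 on 1 of 3 arrays). Cldn5, the main claudin of brain endothelium, was higher by 7.17 ± 0.35 and reached 15.00 ± 0.06 in fragments. Adjusted over the list alone, 20 and 11 members passed in these lists.

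Of 17 pericyte genes 16 were higher (16 adjusted over the list alone), with a median of 2.46 (camera adjusted p = 1.76e-07, adjusted p = 0.139 with an estimated correlation). Foxf2, a transcription factor of brain pericytes, was higher by 5.74 ± 0.16 and the adhesion molecule Mcam by 4.41 ± 0.28, while Dlk1 had a difference of 0.82 (adjusted p = 0.382). Among 11 genes of vascular smooth muscle 7 were higher (7 adjusted over the list alone; median 2.66, camera adjusted p = 0.00202, adjusted p = 0.198 with an estimated correlation). Smtn, of contractile smooth muscle, was at least 56.6-fold higher, and Tagln, an actin-binding protein, was higher by 4.14 ± 0.32 (rest of brain under 4 on 1 of 3 arrays). Cnn1, Lmod1, Pln and Mustn1 lay under 4 on every embryonic array, and cyclic loess between arrays gave them called differences, of 1.71, 2.02, 1.02 and 1.89. Mustn1 passed with the 2 groups fitted alone as well (adjusted p = 0.0315). All 13 basement membrane genes were higher (13 adjusted over the list alone; median 2.97, camera adjusted p = 2.45e-07, adjusted p = 0.0650 with an estimated correlation), among them Lama4, a laminin chain of vessels, by 4.56 ± 0.16 and Nid2, a nidogen, by 4.29 ± 0.16. Fibroblast and meningeal genes went the other way, with 10 of 13 lower and 1 higher (10 and 1 adjusted over the list alone; median -1.63, camera adjusted p = 0.0102, adjusted p = 0.248 with an estimated correlation). Slc6a13, a GABA transporter of the leptomeninges, fell by 2.91 and Islr fell by 2.78. The growth factor Igf2 was higher by 1.04 ± 0.13. Col3a1 and Cemip had differences of -0.33 and -0.58 and were not called, although Cemip passed without adult fragments replicate 2 (adjusted p = 0.0139) and with the embryonic arrays fitted alone (adjusted p = 0.0208).

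Genes of angiogenic sprouting were higher in embryonic fragments in 12 of 14 cases (12 adjusted over the list alone; median 4.99, camera adjusted p = 1.13e-06, adjusted p = 0.0650 with an estimated correlation). Flt4, a receptor of VEGF-C, was at least 163-fold higher and Aplnr, the apelin receptor, was higher by 7.93 ± 0.58. Pgf and Cxcr4 had differences of 0.43 and 0.54 and were not called. Pgf passed after quantile normalization once more and after cyclic loess, at 0.82 and 0.92. Cxcr4 passed without adult fragments replicate 1 (adjusted p = 0.0151), with cyclic loess, array weights, a floor or an offset on low values, or the embryonic arrays fitted alone (adjusted p = 0.00972 to 0.0447 over these). In the list of Notch and arterial genes 10 of 11 were higher and 1 lower (10 and 1 adjusted over the list alone; median 2.80, camera adjusted p = 7.42e-05, adjusted p = 0.0650 with an estimated correlation). Sox17 led this list too, Gja4, a connexin of arteries, was higher by 5.76 ± 0.18, and Efnb2, the arterial ephrin ligand, fell by 0.91. Of 12 genes of Wnt signalling at the barrier 10 were higher (10 adjusted over the list alone; median 2.38, camera adjusted p = 1.44e-05, adjusted p = 0.112 with an estimated correlation). The transcription factor Foxq1, measured by a probe set open to cross-hybridization, was higher by 7.10 ± 0.26. Adgra2, a coreceptor of Wnt7 ligands, was higher by 6.22 ± 0.24. Tspan12 and Ctnnb1 had differences of -0.09 and 0.09 and were not called.

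All 20 neuronal genes were lower in fragments (20 adjusted over the list alone), with a median of -5.55, or -5.37 at the bound (camera adjusted p = 2.12e-08, adjusted p = 0.174 with an estimated correlation). Syt1, the calcium sensor of synaptic vesicles, fell by 6.88. Of 13 genes of neural progenitors 11 were lower and 2 higher (11 and 2 adjusted over the list alone; median -3.83, camera adjusted p = 0.00219, adjusted p = 0.227 with an estimated correlation). Dlx1, a transcription factor of interneurons, fell by 6.45 and Pax6, one of radial glia, fell by 5.64. The higher members, Nes (1.48 ± 0.16) and Vim (0.71 ± 0.13), encode intermediate filaments that vascular cells make as well. Astrocyte genes were lower in 9 of 11 cases and higher in 1 (9 and 1 adjusted over the list alone; median -3.58, or -3.48 at the bound, camera adjusted p = 0.00705, adjusted p = 0.248 with an estimated correlation). The glutamate transporter Slc1a2 fell by 6.74 and the membrane protein Mlc1 fell by 5.05. Glul, glutamine synthetase, was higher by 0.67 ± 0.10, and Gja1, connexin 43, was not called at -0.19, although it passed with cyclic loess (-0.30) and with array weights (-0.24). In the oligodendrocyte lineage 10 of 12 genes were lower and 1 higher (10 and 1 adjusted over the list alone; median -3.26, camera adjusted p = 0.00368, adjusted p = 0.248 with an estimated correlation). The receptor Gpr17 was at least 17.6-fold lower, the transcription factor Olig2 fell by 5.06, and Mal, a membrane proteolipid also found outside myelin, was higher by 6.82 ± 0.32. Of these genes, Syt1, Pax6, Slc1a2 and Olig2 lay under 4 on 2 of 3 fragment arrays, and Mal on 2 of 3 of rest of brain. Mobp lay under 4 on every embryonic array, where cyclic loess turned a difference of -0.01 into 1.89.

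All 17 microglia and macrophage genes were higher in embryonic fragments (17 adjusted over the list alone; median 3.17, camera adjusted p = 2.09e-05, adjusted p = 0.328 with an estimated correlation), beside the vascular lists. Mrc1, the mannose receptor of perivascular macrophages, was higher by 4.78 ± 0.31, and C1qb, a subunit of complement C1q, by 3.98 ± 0.44. Of 15 genes of antigen presentation and interferon response 10 were higher (10 adjusted over the list alone; median 3.01, or 2.57 at the bound, camera adjusted p = 2.69e-04, adjusted p = 0.248 with an estimated correlation). Among the 10 was Ifit1, which lay under 4 on every embryonic array, so that its call is a difference between values at background. Bst2, a membrane protein that tethers viruses, was higher by 4.08 ± 0.38, and Psmb9, a subunit of the immunoproteasome, at least 7.28-fold. H2-Aa and H2-Ab1, the chains of an MHC class II molecule, and Ifit3 lay under 4 on every embryonic array, and cyclic loess turned the differences of H2-Aa and H2-Ab1 from -0.07 and -0.10 to 0.93 and 1.05 and gave Ifit3 a called 0.99. Cd74 and Tap1 were not called at 0.34 and 0.79, although Tap1 passed without embryonic fragments replicate 1 (adjusted p = 0.0353) or adult fragments replicate 3 (adjusted p = 0.0388), and with quantile normalization once more, cyclic loess or array weights (adjusted p = 7.63e-04 to 0.0388 over these). Immediate early and heat shock genes were higher in 15 of 16 cases (15 adjusted over the list alone; median 2.66, camera adjusted p = 1.01e-06, adjusted p = 0.161 with an estimated correlation). Klf2, a transcription factor induced by blood flow, was higher by 6.74 ± 0.19 and Atf3, one induced by stress, by 5.86 ± 0.41 (rest of brain under 4 on 1 of 3 arrays). Egr1 was not called at 0.31 but passed without rest of brain replicate 1 (adjusted p = 0.0221).

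The remaining lists did not pass the list test. Of 6 genes of red cells and platelets 3 were higher (3 adjusted over the list alone; median 1.86, or 1.00 at the bound, camera adjusted p = 0.173). Hbb-y, an embryonic globin measured by a probe set open to cross-hybridization, was at least 16.7-fold higher. The platelet chemokine Ppbp was at least 4.01-fold higher (adjusted p = 0.0219), a call lost without rest of brain replicate 1, 2 or 3 or embryonic fragments replicate 3, or with no filter, a floor or an offset on low values (adjusted p = 0.0540 to 0.0943). Of 9 choroid plexus and ependymal genes 3 were lower (3 adjusted over the list alone; median -1.12, camera adjusted p = 0.166). The transcription factor Otx2 fell by 3.26. Foxj1, which governs motile cilia, was at least 2.25-fold lower, and cyclic loess left it uncalled at -0.33. Genes of cell proliferation were split, with 3 of 22 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.666), and their median (0.03), mean (-0.01) and test (up) differed in sign. Cdk1, the kinase that starts mitosis, was higher by 0.97 ± 0.28, a call lost without rest of brain replicate 3 (adjusted p = 0.0527). The replication helicase subunits Mcm3 and Mcm7 had differences of 0.79 and -1.03, both called. Of 20 genes of oxidative phosphorylation 1 was higher and 2 were lower, and none passed adjusted over the list alone (median -0.17, camera adjusted p = 0.545). Ndufv2 (-0.32), Cox5b (-0.26) and Ndufv1 (0.33) were the called members. Ndufv2 lost its call without embryonic fragments replicate 1 or 3 or rest of brain replicate 1, or with another of its probe sets (adjusted p = 0.0617 to 0.169). Ndufv1 lost it without any 1 of the embryonic fragment arrays or without rest of brain replicate 1 or 2, and with quantile normalization once more, cyclic loess or no probe sets open to cross-hybridization (adjusted p = 0.0504 to 0.257). Cox5b lost it without any 1 array but adult fragments replicate 3 (adjusted p = 0.0547 to 0.156), with replicate number as a block (adjusted p = 0.0788), with arrays centred on their medians, as a mean over probe sets, and among every probe set (adjusted p = 0.0547 to 0.182 over the whole).

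**Figure D1:**
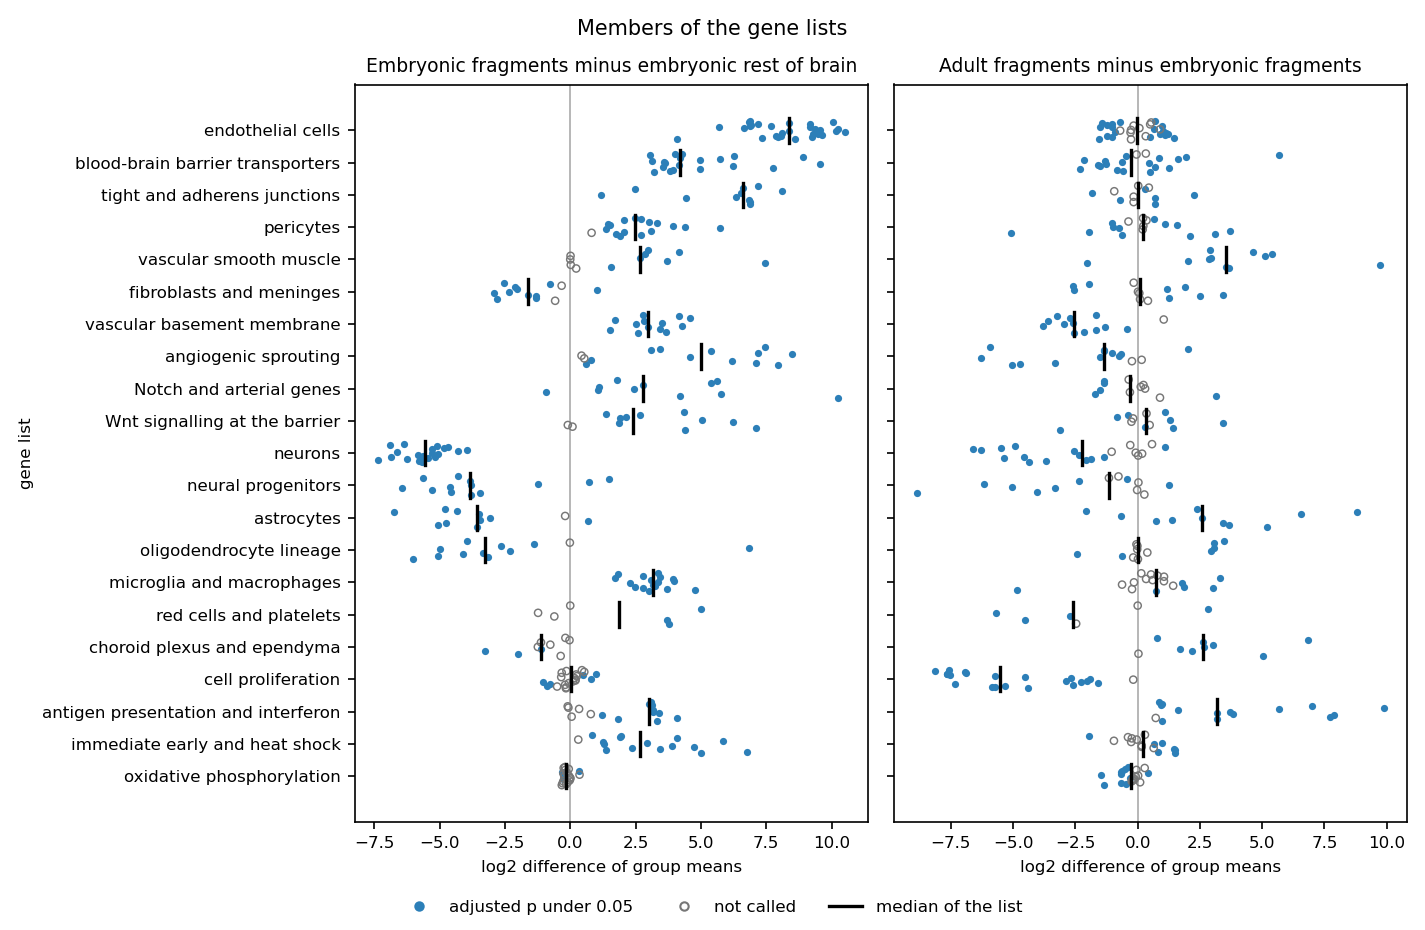
Log2 differences of the tested members of the 21 gene lists, for embryonic fragments minus embryonic rest of brain (left) and adult minus embryonic fragments (right). Each point is a gene, blue where limma's adjusted p was under 0.05 and open grey where it was not, and the black bar is the list's median, which for endothelial cells lies at 8.35 on the left and -0.05 on the right and for cell proliferation at 0.03 and -5.52.

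Adult and embryonic fragments were compared to ask how the transcripts of brain microvessels differ between embryonic day 18.5 and 1 year of age. Adult fragments held far less RNA of genes of cell proliferation and less of those of basement membrane and angiogenic sprouting. They held more of vascular smooth muscle, antigen presentation and interferon genes, while the endothelial and junction lists had no called shift. None of the 5 shifted lists kept its call with an estimated correlation (adjusted p = 0.220 to 0.321 with an estimated correlation). Top2a, the topoisomerase of dividing cells, fell by 8.13 in adults (3.62 ± 0.89, under 4 on 2 of 3 arrays, against 11.76 ± 0.09, limma adjusted p = 5.01e-07). H2-Aa, of MHC class II, was at least 249.7-fold higher (11.96 ± 0.65 against 2.08 ± 0.10, adjusted p = 3.06e-08). Of 12009 genes, 3289 were higher and 3565 lower in adult fragments (57.1% in all) and 5155 were not called, with at least 2-fold differences in 1891 and 1838. Embryonic fragments lay under 4 on every array for 282 of the higher genes and adult fragments for 282 of the lower ones. Strain (NMRI embryos, mixed C57/SV129 adults) and RNA kit differed together with age in the labels and cannot be told apart from it. Adult arrays also had larger 3' to 5' differences, of 2.46 ± 0.53 against 1.23 ± 0.04 for Actb and 2.58 ± 0.16 against 2.05 ± 0.04 for Gapdh (log2, exact permutation p = 0.1 each, the smallest that 3 arrays against 3 can give).

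The rule named among higher genes Gh, growth hormone, H2-Aa, Pln, which regulates the calcium pump of muscle, Sgpp2, a phosphatase of sphingosine 1-phosphate, and Iigp1, an interferon-induced GTPase. Gh reached 13.59 ± 1.31 in adult fragments and was at least 771-fold higher, but it was also at 8.02 and 10.1 in rest of brain replicates 2 and 3. Pln and Iigp1 were at least 241-fold and 162-fold higher, and Sgpp2 was higher by 9.17 ± 0.10. Among lower genes it named Sox11, a transcription factor of immature neurons, Hif3a, Fcna, a ficolin of macrophages, Top2a and Lyve1, a hyaluronan receptor of lymphatic endothelium and macrophages. Sox11 and Fcna lay under 4 on every adult array and were at least 146-fold and 137-fold lower, while Hif3a, under 4 on 2 of 3 adult arrays, and Lyve1 had differences of -8.81 and -7.76.

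In the list of cell proliferation 21 of 22 genes were lower in adult fragments (21 adjusted over the list alone). The median was -5.52, or -5.31 at the bound (camera adjusted p = 7.04e-13, adjusted p = 0.220 with an estimated correlation). Cdk1 fell by 7.66 to 3.65 ± 0.65 (under 4 on 2 of 3 adult arrays), and Mcm4 was not called at -0.18, although it was at -0.78 as a mean over its probe sets and at -1.38 without probe sets open to cross-hybridization, both called. Of 13 basement membrane genes 12 were lower (12 adjusted over the list alone; median -2.56, or -2.17 at the bound, camera adjusted p = 8.27e-06, adjusted p = 0.220 with an estimated correlation). Nid2 fell by 3.79 and the laminin chain Lamb1 fell by 3.60, and Lama5 was not called at 1.05 but was at 1.33, as a mean over its probe sets. Genes of angiogenic sprouting were lower in 11 of 14 cases and higher in 1 (11 and 1 adjusted over the list alone; median -1.35, camera adjusted p = 9.76e-04, adjusted p = 0.321 with an estimated correlation). Cxcr4, a chemokine receptor of tip cells, fell by 6.31 (under 4 on 2 of 3 adult arrays), and Apln, the apelin ligand, fell by 5.94. Nrp1 and Plvap were not called at 0.16 and -0.23, and the difference of Nrp1 was -0.66 as a mean over its probe sets (adjusted p = 0.00127). Esm1, a proteoglycan of tip cells, was higher by 2.03 ± 0.67 (adjusted p = 0.0300), a call lost without any 1 of the embryonic fragment arrays or without adult fragments replicate 2 or 3, and with no filter on low values or with array weights (adjusted p = 0.0526 to 0.0903). These lists moved beside lower neuronal and progenitor genes and higher 3' to 5' differences on the adult arrays.

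Endothelial markers were split between the ages, with 10 of 30 higher and 10 lower in adults (10 and 10 adjusted over the list alone; median -0.05, camera adjusted p = 0.850). Myct1 was higher by 1.45 ± 0.33 and Cd93, a receptor of endothelial adhesion, fell by 1.53. Mmrn2, an endothelial matrix protein, was higher by 1.21 ± 0.36, a call lost without embryonic fragments replicate 2 or 3 or adult fragments replicate 1, or with no filter on low values (adjusted p = 0.0513 to 0.0549). Barrier transporters were higher in 8 of 20 cases (9 adjusted over the list alone) and lower in 10 (10 adjusted over the list alone). The median of this list was -0.26, its mean 0.03 and its test pointed down (camera adjusted p = 0.867). Slco1a4, an organic anion transporter, was 51.4-fold higher in adults (15.29 ± 0.10 against 9.61 ± 0.12). Mfsd2a, which carries docosahexaenoic acid as a lysolipid, fell by 2.33, and Slc7a5, a carrier of large neutral amino acids, fell by 2.16. Of 11 junction genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone; median 0.02, camera adjusted p = 0.663). Jam2 and Cgnl1 were higher by 2.26 ± 0.20 and 0.71 ± 0.16, and Marveld2, tricellulin, fell by 1.82. The Notch and arterial list had 1 higher and 4 lower genes of 11 (1 and 4 adjusted over the list alone; median -0.31, camera adjusted p = 0.459). Bmx, a kinase of arterial endothelium, was higher by 3.14 ± 0.22, while Gja4 fell by 1.72 and Nrarp, a feedback inhibitor of Notch, was at 11.01 ± 0.16 against 12.51 ± 0.17 in embryonic fragments. In the Wnt list 5 of 12 genes were higher and 3 lower (5 and 3 adjusted over the list alone; median 0.32, camera adjusted p = 0.459). Reck, a coreceptor of Wnt7, was higher by 3.44 ± 0.12, and the nuclear receptor Ppard fell by 3.11. Foxq1 was higher by 1.44 ± 0.26 on a probe set open to cross-hybridization, and its difference was -0.18 (adjusted p = 0.284) without probe sets of that kind.

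Vascular smooth muscle genes were higher in adult fragments in 10 of 11 cases and lower in 1 (10 and 1 adjusted over the list alone; median 3.55, or 2.94 at the bound, camera adjusted p = 1.34e-05, adjusted p = 0.220 with an estimated correlation). Besides Pln, Myh11, the smooth muscle myosin, was higher by 5.42 ± 0.47, and Smtn fell by 2.02. Astrocyte and choroid plexus genes (medians of 2.597 and 2.62, the latter 1.69 without embryonic fragments replicate 1) and the 3' to 5' difference of Actb (2.46 ± 0.53 against 1.23 ± 0.04) were higher in adult fragments beside this list and beside that of antigen presentation and interferon. Pericyte genes were split, with 6 of 17 higher and 6 lower (6 and 6 adjusted over the list alone; median 0.22, camera adjusted p = 0.459). Art3 and the aminopeptidase Enpep were higher by 3.70 ± 0.17 and 3.09 ± 0.13, and Dlk1, a growth factor precursor, was at least 25.5-fold lower. Of 13 fibroblast and meningeal genes 5 were higher and 3 lower (5 and 3 adjusted over the list alone; median 0.10, camera adjusted p = 0.556). Ogn, a small proteoglycan, and Serping1, the C1 inhibitor, were higher by 3.44 ± 0.29 and 2.50 ± 0.16, and the collagen Col3a1 fell by 2.61.

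Of 15 genes of antigen presentation and interferon response 14 were higher in adult fragments (14 adjusted over the list alone; median 3.18, camera adjusted p = 4.97e-07, adjusted p = 0.321 with an estimated correlation). Ifit1, an interferon-induced RNA-binding protein, was at least 151-fold higher. Bst2 was not called at 0.73 but was at 1.24 without adult fragments replicate 1 (adjusted p = 5.40e-04). Of 17 microglia and macrophage genes, 5 were higher (4 adjusted over the list alone) and 1 lower (1 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.249). Itgam, an integrin of myeloid cells, and Tmem119, a microglial membrane protein, were higher by 3.31 ± 0.63 (under 4 on 1 of 3 embryonic arrays) and 3.02 ± 0.75, and Mrc1 fell by 4.84. Immediate early and heat shock genes were higher in 6 of 16 cases and lower in 1 (6 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.337). The transcription factor Klf4 and Btg2, an antiproliferative gene, were higher by 1.51 ± 0.11 and 1.49 ± 0.18, and Fosb fell by 1.95. Among 6 genes of red cells and platelets 1 was higher and 3 were lower (1 and 3 adjusted over the list alone; median -2.58, camera adjusted p = 0.249). Alas2, of heme synthesis in red cells, was at least 29.8-fold lower and the platelet chemokine Pf4 fell by 4.52, while Hbb-y, measured by a probe set open to cross-hybridization, was higher by 2.82 ± 0.20.

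Markers of cells around the vessels differed between the ages too. Neuronal genes were lower in adult fragments in 13 of 20 cases and higher in 1 (13 and 1 adjusted over the list alone; median -2.23, or -2.06 at the bound, camera adjusted p = 2.15e-04, adjusted p = 0.432 with an estimated correlation). Rbfox3, the neuronal nuclear antigen, and Dcx, a microtubule protein of migrating neurons, were at least 26.1-fold and 25.9-fold lower. Stmn2 was higher by 1.09 ± 0.31, a call lost without adult fragments replicate 1 (adjusted p = 0.0525) and, at 0.61, as a mean over its probe sets (adjusted p = 0.0631). Of 13 progenitor genes 7 were lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.0121, adjusted p = 0.432 with an estimated correlation), with a median of -1.15 that was -0.51 without embryonic fragments replicate 2. Fabp7, a fatty acid binding protein of radial glia, fell by 6.19, and the glutamate transporter Slc1a3 was higher by 1.26 ± 0.25. The uncalled members were Sox2 (-0.77), Pax6 (-1.15), Vim (0.03, or -0.62 without probe sets open to cross-hybridization), and Dlx2 and Msi1, which lay under 4 on every fragment array. Sox2 passed without embryonic fragments replicate 1 (adjusted p = 0.0316) or adult fragments replicate 3 (adjusted p = 0.0169) or with array weights (adjusted p = 0.0144), and Pax6 without embryonic fragments replicate 1 (adjusted p = 0.0338). Astrocyte genes were higher in 9 of 11 cases and lower in 2 (9 and 2 adjusted over the list alone; median 2.597, camera adjusted p = 0.00377, adjusted p = 0.394 with an estimated correlation). Slc1a2 was higher by 8.80 ± 0.71 (12.35 ± 0.48 against 3.55 ± 1.56, under 4 on 2 of 3 embryonic arrays) and S100b, a calcium-binding protein, was higher by 6.57 ± 0.57 (under 4 on 2 of 3 embryonic arrays). Gja1 fell by 0.66 and Aldh1l1, of folate metabolism and under 4 on 1 of 3 adult arrays, fell by 2.07, the latter a call lost without embryonic fragments replicate 2 or with the 2 groups fitted alone (adjusted p = 0.0574 and 0.0574).

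Choroid plexus and ependymal genes were higher in adult fragments in 8 of 9 cases (8 adjusted over the list alone; camera adjusted p = 7.78e-04, adjusted p = 0.394 with an estimated correlation). Their median was 2.62, and 1.69 without embryonic fragments replicate 1. Kl, the coreceptor klotho, and Slc4a5, a bicarbonate transporter, were at least 38.2-fold and 14.9-fold higher, and Foxj1 lay under 4 on every fragment array. In the oligodendrocyte lineage 4 of 12 genes were higher and 2 lower (4 and 2 adjusted over the list alone; median 0.00, camera adjusted p = 0.366). The myelin genes Mbp and Mal were higher by 3.48 ± 0.45 and 3.08 ± 0.32, and the transcription factor Olig1 fell by 2.45. Genes of oxidative phosphorylation were lower in 10 of 20 cases and higher in 1 (10 and 1 adjusted over the list alone; median -0.27, camera adjusted p = 0.0425, adjusted p = 0.432 with an estimated correlation). This list's call was lost with replicate number as a block (adjusted p = 0.0562), although no pairing of adult with embryonic arrays is known. It was also lost with cyclic loess (adjusted p = 0.130), with arrays centred on their medians (0.0677), with a filter at a value of 6 (0.0567), and without embryonic fragments replicate 2 (adjusted p = 0.0637) or 3 (0.0542) or adult fragments replicate 1 (0.0621) or 3 (0.0524). Uqcrc1, of complex III, fell by 1.48 and Atp5o, of the ATP synthase, fell by 1.33. Sdha, of complex II, was higher by 0.41 ± 0.15 (adjusted p = 0.0435), a call lost without any 1 array but adult fragments replicate 2, and in 5 of the other settings (adjusted p = 0.0514 to 0.117), with a difference of 0.25 without adult fragments replicate 3.

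**Figure D2:**
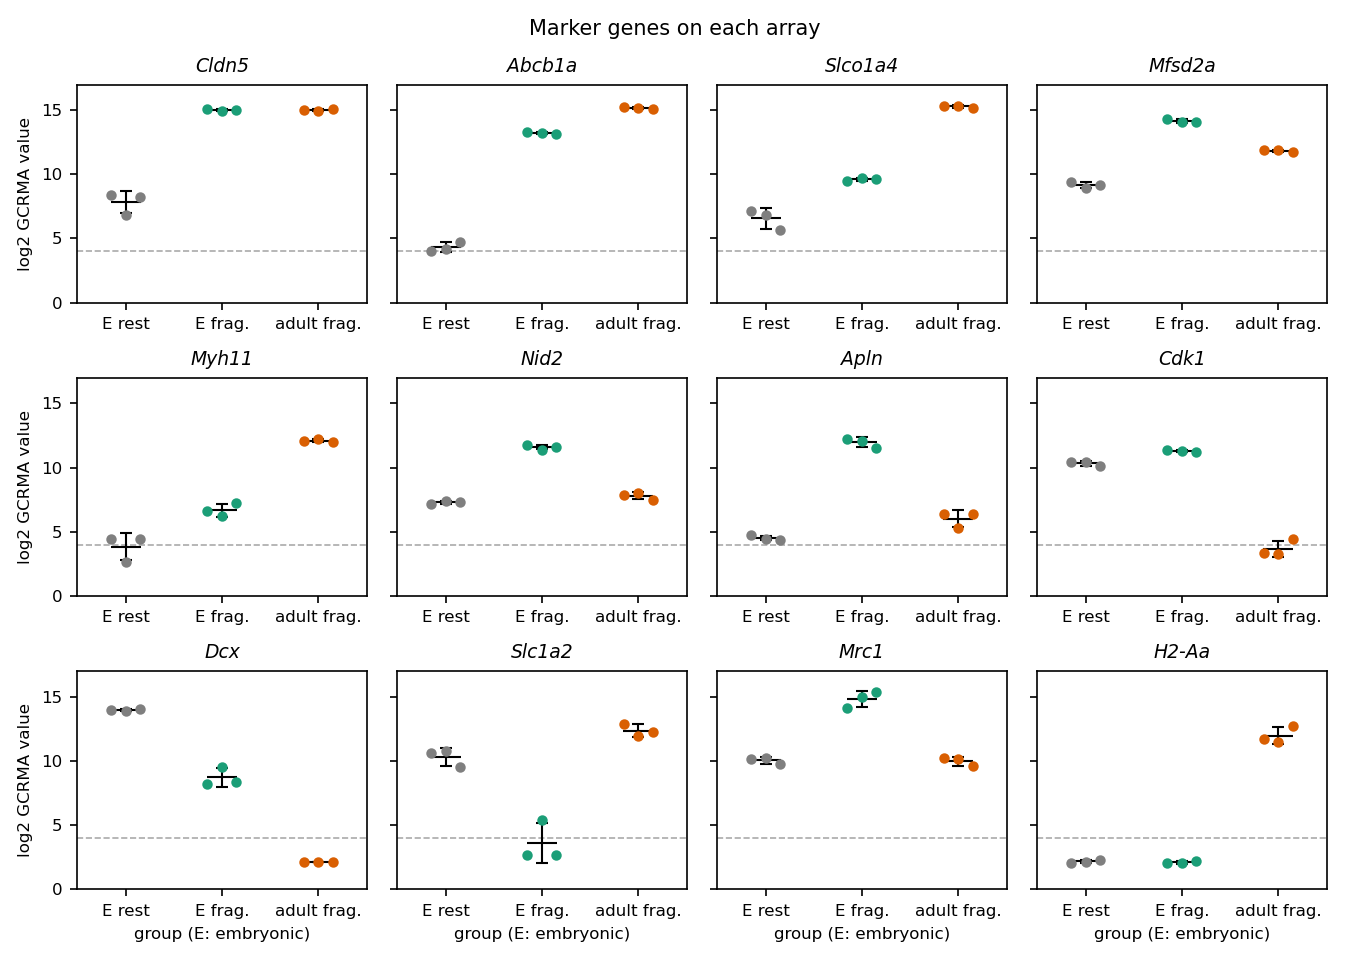
Log2 GCRMA values of 12 genes on each array, grouped as embryonic rest of brain, embryonic fragments and adult fragments. Points are arrays, bars are the mean ± SD over 3 arrays, and the dashed line marks the value of 4; Cldn5 has a mean of 15.00 in embryonic and 15.03 in adult fragments, whereas Cdk1 has 11.31 and 3.65.

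Adult fragments and embryonic rest of brain differ in tissue, age, strain and RNA kit, and this comparison served to find genes higher in fragments of both ages. Sox17 and Vwf, under 4 on 2 of 3 arrays of rest of brain, and Abcb1a were higher in adult fragments by 11.13 ± 0.37, 11.19 ± 0.19 and 10.85 ± 0.18, and Cyyr1 and the adhesion receptor Adgrl4 were at least 1205-fold and 1015-fold higher. Sox11, Dcx, Crmp1, Neurod6 and Pcdh8, genes of developing neurons, lay under 4 on every adult array and were at least 1613-fold, 1003-fold, 1008-fold, 715-fold and 385-fold lower. All 30 endothelial markers were higher (30 adjusted over the list alone; median 8.43, or 7.58 at the bound, camera adjusted p = 1.03e-15, adjusted p = 0.134 with an estimated correlation), and all 20 neuronal genes were lower (20 adjusted over the list alone; median -8.21, or -8.11 at the bound, camera adjusted p = 2.70e-08, adjusted p = 0.174 with an estimated correlation). Of 12009 genes 3975 were higher and 5157 lower (76.0% in all), and 2877 were not called.

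Genes higher than in rest of brain in fragments of both ages numbered 2645, of which 311 lay under 4 on every rest of brain array, and 3505 were lower in both. Of the former, 13 lay under 4 on every array of both embryonic groups, so that their call in embryonic fragments is a difference between values at background. Independent lists of these sizes would share 1149.57 higher and 1917.83 lower genes, and 20 simulations of unchanged groups against the same rest of brain arrays gave a mean overlap of 0. Unchanged groups leave next to no calls to overlap, so this value says nothing of comparisons that hold real effects. With only 3 rest of brain arrays the controls could not be split, and part of the excess may come from the shared controls. Between the ages, 1003 of the 2645 genes were higher and 484 lower in adult fragments, and 1158 were not called. Another 227 genes were higher in embryonic but lower in adult fragments than in rest of brain. Among the 2645, the rule named as higher with age Ifit1 and Layn, a hyaluronan receptor (at least 36.5-fold between the ages), both among these 13, and Gkn3, a gastrokine (7.82 ± 0.40), AW112010 (6.53 ± 0.48) and Degs2, a sphingolipid desaturase (6.07 ± 0.17). Gkn3 was called in embryonic fragments against rest of brain at adjusted p = 0.0473. It named as lower Apln and its receptor Aplnr, which fell by 5.05 to 9.71 ± 1.27. Itga4, an integrin of adhesion to VCAM1, Slco2a1, a prostaglandin transporter, and Pcdh12, a protocadherin of endothelium, lower too, had differences of -5.03, -5.02 and -4.86.

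**Figure D3:**
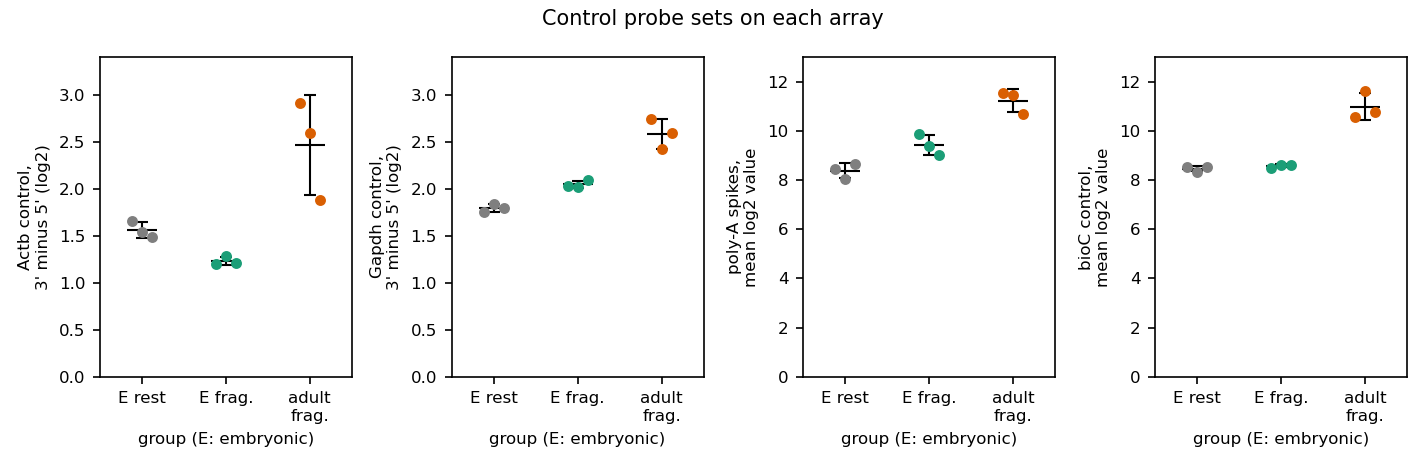
Control probe sets on each array, with the 3' minus 5' difference of Actb and of Gapdh, the mean of the poly-A spikes and the mean of the bioC hybridization control, all in log2 units. Points are arrays and bars the mean ± SD over 3 arrays; the Actb difference is 2.46 ± 0.53 in adult fragments, 1.23 ± 0.04 in embryonic fragments and 1.56 ± 0.09 in rest of brain.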

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

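The splits of the arrays were tests chosen only after the results were seen, whereas the test of second probe sets was written before its result was seen.

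Signals of the poly-A spikes and of hybridization controls differed between groups, to unlike degrees. The poly-A spikes, added to the RNA before labelling, were 1.05 higher (log2) in embryonic fragments than in rest of brain (9.43 ± 0.42 against 8.38 ± 0.32, n = 3, exact permutation p = 0.1). On adult fragment arrays they were at 11.22 ± 0.47, which is 1.79 above embryonic fragments and 2.84 above rest of brain (exact permutation p = 0.1 each). The hybridization control bioC was 2.401 higher on adult than on embryonic fragment arrays (10.98 ± 0.57 against 8.58 ± 0.07, n = 3, exact permutation p = 0.1). The other hybridization controls differed less. They were higher on adult arrays by 0.62 for bioB (9.46 ± 0.68 against 8.84 ± 0.01, exact permutation p = 0.1) and by 0.42 for bioD (14.04 ± 0.43 against 13.62 ± 0.07, exact permutation p = 0.2). Among 2242 tested probe sets without a gene name here, 1062 were higher and 476 lower in embryonic fragments than in rest of brain, and 417 were higher and 799 lower in adult than in embryonic fragments (limma adjusted p under 0.05).

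Differences between the ages stood beside larger 3' to 5' differences on the adult arrays. Among called genes with differences of 1 to 3 (log2), the next probe set of the gene went the same way for 84.6% of 1280 genes between the ages and for 93.8% of 1351 genes between embryonic fragments and rest of brain. Between adult fragments and rest of brain, where the adult arrays also enter, it was 89.2% of 1679 genes. The difference of the first 2 was -9.17 percentage points (95% confidence interval -11.5 to -6.81). That interval treats genes as independent, although both comparisons share the embryonic fragment arrays, and does not measure the spread over arrays. The difference itself lies between the bounds set beforehand for a bias of the adult RNA or its amplification and for its absence. Its interval reaches past the bound for a bias and lies wholly outside that for its absence. Such a bias may account for part of the age differences and stays open. Age itself, strain and transcript isoforms that differ with age stay open too and were not tested.

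Splits of the arrays other than by group were fitted in the same way. Of the 10 splits of 6 arrays into 3 and 3, only the real one (1 of 10) gave as many called genes in each comparison. The real split called 7939 genes between embryonic fragments and rest of brain (highest other split 0, also among the 4 splits that part all 3 pairs of embryonic samples), 6854 between the ages (highest other 15) and 9132 between adult fragments and rest of brain (highest other 0). These splits are too few for a share under 0.05. Of 100 drawn splits of the 9 arrays into 3 groups, 1 of 100, the real one, gave 2645 genes higher in both fragment groups (highest other 2167) and 1 of 100, again the real one, gave as many age changes among such genes (1003 higher and 484 lower in adults, against at most 788 in all in the other splits). The drawn splits moved the 9 arrays freely. Among the 53 that part all 3 embryonic pairs, as the real one does, the real one alone (1 of 53) gave as many in both cases, with the same highest others, and those that part fewer pairs gave at most 1362 and 0. The real grouping alone reached either count, a share under 0.05. That share is descriptive, since the splits were chosen late and the embryonic arrays are not free to be exchanged. Groups that differ this much also leave few calls once they are mixed. The counts of the other splits point to the structure of the 3 groups, which a split may keep in part.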

How the results depend on the processing

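The test of the 6 embryonic arrays alone with the replicate block, and that of genes with both means of at least 4, were chosen only after the results were seen. Across the alternatives, 213 counts stayed within 1.5 times the reported count and 15 did not. Every probe set tested singly gave more calls because more units were tested: 7230 higher and 7678 lower for embryonic fragments against rest of brain, 5569 and 7453 for adult against embryonic fragments, 7394 and 9367 for adult fragments against rest of brain, and 4921 higher in both fragment groups, of which 1565 were higher and 1069 lower in adults. A threshold of 0.01 left 283 genes higher in both fragment groups but lower in adults, and at least 2-fold differences left 2845 lower in embryonic fragments than in rest of brain, 1891 higher and 1838 lower in adult fragments, and 461 higher and 186 lower among those higher in both, by construction. With the replicate block the counts were 3485 and 4502 for embryonic fragments against rest of brain, 3328 and 3566 between the ages, 3988 and 5168 for adult fragments against rest of brain, and 2668 higher in both; the block ended the calls of the oxidative phosphorylation list between the ages and of Cox5b in embryonic fragments against rest of brain, and changed no other call of a list or named gene in the 3 comparisons. In the comparisons with adult fragments the block follows no known pairing. The 6 embryonic arrays alone with the block gave 3622 and 4711. Genes with both means of at least 4 numbered 3026 and 3645 between embryonic fragments and rest of brain and 2947 and 3212 between the ages.

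Leaving out each array in turn gave 3167 to 3657 higher and 4071 to 4694 lower genes for embryonic fragments against rest of brain, 2982 to 3221 and 3124 to 3816 between the ages, and 3719 to 4001 and 4833 to 5318 for adult fragments against rest of brain. It gave 2461 to 2666 genes higher in both, of which 856 to 979 were higher and 401 to 482 lower in adults. The share of higher genes among the calls was 43.7%, 48.0% and 43.5% in the 3 comparisons, and 44.3%, 49.7% and 45.0% with arrays centred on their medians. Cyclic loess moved this balance further. It gave 4271 higher and 4196 lower genes for embryonic fragments against rest of brain, 3432 and 3516 between the ages, and 4680 and 4781 for adult fragments against rest of brain. Quantile normalization once more gave 4057 and 4271, 3227 and 3674, and 4430 and 5014. Of the list results in the 3 comparisons, 1391 kept a call in the same direction or stayed uncalled, whichever direction the uncalled ones took. Another 50 lost their call, 41 of them with an estimated correlation. The others were those of the oxidative phosphorylation list between the ages and, as a mean over probe sets, of the basement membrane list in adult fragments against rest of brain (adjusted p = 0.0655). A call was gained by 28, of which 12 with fry, and the rest were lists of adult fragments against rest of brain. There the test of red cells and platelets (median -0.40), uncalled with camera, changed its direction with fry. Of the results of added lists 576 stayed, 9 lost and 9 gained a call, and of those of named genes 4757, 84 and 40, with 6 reversed. The reversed values of genes were those of Mobp (1.89), H2-Ab1 (1.05) and H2-Aa (0.93) in embryonic fragments against rest of brain under cyclic loess, where both groups lay under 4 beforehand. Between the ages they were those of Nrp1 (-0.66) as a mean over its probe sets, and of Foxq1 (-0.18) and Vim (-0.62) without probe sets open to cross-hybridization, which moves these genes to another probe set by construction. The cause was not tested for the others. Signal over background limits genes under 4 in a group, for which a bound alone can be given.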

Other observations

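The 11 gene lists described here and the test of immediate early genes were chosen only after results had been seen, whereas the tests of pituitary hormones, but for that of Cga and Prl, were written before their results were seen.

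Since these lists were chosen with the values known, their p-values are no independent evidence of a direction. Genes of interferon-inducible GTPases and of xenobiotic metabolism were mostly higher in adult than in embryonic fragments, and imprinted growth genes and markers of lymphatic endothelium mostly lower. In the same comparison astrocyte and choroid plexus lists had medians of 2.597 and 2.62 (1.69 without embryonic fragments replicate 1), neuronal and progenitor lists of -2.23 and -1.15 (-0.51 without embryonic fragments replicate 2), and the 3' to 5' difference of Actb was 2.46 ± 0.53 on adult against 1.23 ± 0.04 on embryonic arrays. All 8 interferon-inducible GTPases were higher in adults (8 adjusted over the list alone; median 2.83, camera adjusted p = 7.51e-06), led by Iigp1 (at least 162-fold), Gbp6 (5.37 ± 0.22) and Gbp2 (4.56 ± 0.14). Of 15 genes of xenobiotic metabolism 12 were higher and 1 lower (12 and 1 adjusted over the list alone; median 2.71, or 2.56 at the bound, camera adjusted p = 7.89e-06). Aldh1a1, a retinaldehyde dehydrogenase, Cyp2e1, a cytochrome P450, and Aox1, an aldehyde oxidase, were at least 132-fold, 70.7-fold and 16.5-fold higher. The glutathione transferase Gstm5 fell by 1.80, and Cyp2j6 (0.90) and Sult1a1 (0.31) were not called, although Cyp2j6 was at 1.41 without adult fragments replicate 2 (adjusted p = 0.00281). Imprinted growth genes were lower in 13 of 14 cases (13 adjusted over the list alone; median -1.74, camera adjusted p = 1.38e-05). Mest fell by 5.64, Plagl1 fell by 3.56 and Dlk1 was at least 25.5-fold lower, while Slc38a4 lay under 4 on every fragment array. Of 8 markers of lymphatic endothelium, some of which macrophages share, 6 were lower (6 adjusted over the list alone; median -3.76, or -2.87 at the bound, camera adjusted p = 0.00344, adjusted p = 0.112 with an estimated correlation). Among these 6, Flt4 also stands on the list of angiogenic sprouting and Reln on that of neurons. Besides Fcna and Lyve1, Mmrn1 fell by 7.72 (under 4 on 2 of 3 adult arrays). Prox1, the regulator of lymphatic identity, lay under 4 on every fragment array and Pdpn was not called at 0.97. Prox1 passed without embryonic fragments replicate 1 (adjusted p = 0.0337) and under cyclic loess (adjusted p = 0.0272), and Pdpn without embryonic fragments replicate 2 (adjusted p = 0.0338) or adult fragments replicate 3 (adjusted p = 0.0478).

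In embryonic fragments against rest of brain, all 6 Gimap genes, GTPases of the immune system, were higher (6 adjusted over the list alone; median 7.73, or 6.47 at the bound, camera adjusted p = 7.51e-05, adjusted p = 0.208 with an estimated correlation), among them Gimap4 (at least 283-fold), Gimap6 (at least 98.1-fold) and Gimap8 (8.04 ± 0.26, rest of brain under 4 on 1 of 3 arrays). Between the ages 1 of them was higher and 2 were lower (1 and 2 adjusted over the list alone; median -0.45, camera adjusted p = 0.537). Of 8 interferon-inducible GTPases 7 were higher in embryonic fragments than in rest of brain (7 adjusted over the list alone; median 4.84, or 4.66 at the bound, camera adjusted p = 1.16e-04, adjusted p = 0.208 with an estimated correlation), among them Irgm2 and Irgm1 (at least 56.0-fold and 24.4-fold) and Gbp3 (5.16 ± 0.17). Iigp1 lay under 4 in both, and cyclic loess gave it a called 1.02. The other lists had no called shift between these tissues. Lymphatic markers had 5 of 8 higher and 3 lower (median 5.27, camera adjusted p = 0.339), and xenobiotic metabolism had 2 of 15 higher and 6 lower (median -0.14, camera adjusted p = 0.768), with the same counts adjusted over the list alone. Imprinted growth genes had 7 of 14 higher (8 adjusted over the list alone) and 4 lower, with a median of 0.58, a mean of -0.04 and a test pointing up (camera adjusted p = 0.731). Glycolysis had 3 of 15 higher (2 adjusted over the list alone) and 4 lower (camera adjusted p = 0.836), and 4 higher and 7 lower between the ages (4 and 7 adjusted over the list alone; camera adjusted p = 0.499), with medians of -0.09 and -0.35. Of 4 neutrophil genes 1 was higher and 2 were lower between the tissues (median -0.92, test up, camera adjusted p = 0.973), and 1 was higher and 1 lower between the ages (median 0.49, mean -0.39, test up, camera adjusted p = 0.879). Of 4 mast cell genes 2 were higher and 2 lower between the tissues (median 0.12, camera adjusted p = 0.836) and 1 was higher and 1 lower between the ages (median -0.02, camera adjusted p = 0.879). Of 2 tested genes of T and B cells, too few for a list test, 1 was higher in embryonic fragments than in rest of brain and 0 were called between the ages.

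Adult fragments held transcripts of 4 pituitary hormone genes, which were put on a list because they were high, so that no list test is given. Their median difference from embryonic fragments was 7.85, or 7.003 at the bound, with Gh at 13.59 ± 1.31, Pomc at 12.07 ± 0.76, Cga at 10.52 ± 1.29 and Prl at 10.29 ± 1.09, and their SDs among adult arrays lay at the 98.0th to 99.7th percentile of 7608 genes with an adult mean of at least 8. The subunits of other pituitary hormones, Tshb, Lhb and Fshb, had adult means of 3.26, 1.37 and 4.64. Between embryonic fragments and rest of brain 2 of the 4 on the list were lower (0 adjusted over the list alone; median -0.59), and rest of brain replicates 2 and 3 had Gh at 8.02 and 10.1. Cross-hybridization of single probe sets is argued against for Gh and Pomc, since 100% of their 4 other probe sets had an adult mean of at least 6, among them 1 of each gene (12.10 and 10.13) whose probes are shared between transcripts of that gene alone. For Cga and Prl, with 0 other probe sets, cross-hybridization stays open. Pituitary tissue carried into the adult preparations may be the source and stays open: the median difference of 10 other pituitary genes was 0.0265, but 9 of them lay under 4 on every array, so that the bound set beforehand decided nothing, and Fshb alone was higher, at 4.64 against 2.09. Hormone transcripts made in adult brain stay open too, as an untested explanation.

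Immediate early and heat shock genes were higher in embryonic fragments than in rest of brain, with a median of 2.66 (adjusted p = 0.161 with an estimated correlation). Handling during the isolation of fragments may account for the pattern only if rest of brain was not handled alike, which the sources used here do not give. Adult fragments, isolated too, had a list median 3.43 above rest of brain (camera adjusted p = 8.13e-06, adjusted p = 0.174 with an estimated correlation). That value cannot decide, since fragments of either age differ from rest of brain in tissue whatever the handling. Handling thus cannot be told apart from higher levels in vessels, which were not tested.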
